A study of Caenorhabditis elegans with 4 samples.

How the data were processed

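Chromatin of C. elegans late embryos was studied, per the labels, in a strain carrying a GFP-tagged copy of the FKH-10 gene, which had been introduced as a transgene together with a rescue marker. Hermaphrodite cultures were grown at 20 °C, and worms were fixed in 2% formaldehyde at the chosen stage, per the labels' protocols. Part of the sonicated lysate was set aside as input DNA and the rest was immunoprecipitated with an anti-GFP antibody, per the labels' protocols. The 4 samples were grouped by their titles into 2 FKH-10 ChIP samples and 2 inputs.

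Peaks were called by the authors with PeakSeq on genome build WormBase WS220, per the file headers and the source column of the lists. PeakSeq compares ChIP reads with a control library. Its version, the aligner, the threshold and how the inputs were used are not given in the sources used here. There were 3 lists, 1 for each ChIP replicate and 1 for the whole series. Whether the series list came from pooled reads or from merged lists is not given in the sources used here. Merging the 2 replicate lists as they stand could not give it, since 1092 of its 1838 peaks overlapped neither. Each peak of the deposited lists carries 1 value, read here as the authors' q-value. The file headers do not name it. The reading rests on the values, which stay below 0.001 and whose product with the peak number never falls, as for p-values adjusted by rank. Peak numbers ran to 1862 in the series list and 722 in replicate 1, so 24 and 11 numbers were not used in those lists, and to 439 with no gap in replicate 2. The q-values were used to rank peaks within a list and never compared between lists. No per-sample read counts were in the lists, so the depth per sample and any effect of depth on the number of peaks are unknown.

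The comparisons, their tests, the rule for named peaks and most alternatives were fixed before the data were examined. Peaks of the replicates were called shared when they overlapped by at least 1 bp. Overlap was compared with 10000 random placements of the other list, with the same widths on the same chromosomes, and the p is one-sided. Ranks of shared and unshared peaks were compared with a 2-sided permutation test of the difference in medians with 100000 resamples, on percentiles of the q order. Correlations over shared pairs used each peak of replicate 2 with the lowest-q peak of replicate 1 that it overlapped, and 10000 permutations of the pairs. Peaks per chromosome and in the middle of the autosomes were compared with 10000 random draws in proportion to length, 2-sided, with Benjamini-Hochberg adjustment over the 6 chromosomes of a list. These random-draw p-values treat each peak as independent, although neighbouring peaks can cluster. Intervals are exact Clopper-Pearson at 95%. The rule named, in the absence of an annotation of the same build, the 20 highest-ranked series peaks overlapping both replicates, by position. The 6 wide blocks, the 20 peaks outside them, the analyses without blocks, the shift of a list by 20 to 200 kb and the use of chains of peaks as units were chosen after the data were seen.

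The alternatives fixed in advance were an overlap of 50% of the shorter peak, windows of 200 bp around midpoints, the stricter 50% of a list, lists of equal length, the middle 50% of the autosomes and each replicate left out. The annotation used here is of assembly WBcel235, and no genome sequence was used. The chromosomes of fkh-10 and unc-119 were taken from it for the text, and positions in it were only looked at informally. Since builds are not mixed in any analysis, those planned of promoter share, annotation classes, the 22 gene lists, the forkhead motif, noncoding RNA genes and the transgene loci were not run. Random placement at promoters was not run either.

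The overlap and median tests were tested on simulated data first. The simulated lists were scattered at random, as in the overlap test's own placements. They held no clusters of peaks, so these runs do not check the overlap test on clustered lists. With 439 simulated peaks, planting 0, 50 and 200 shared peaks gave 0.768, 50.0 and 199 peaks above random, and 0, 5 and 5 of 5 runs passed 0.05. For the median test, 0 of 20 runs passed with no planted difference and 19 of 20 with a planted difference of 20 points. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.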

Results

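ChIP-seq was performed, per the labels, for FKH-10, a forkhead (winged-helix) transcription factor, in late embryos of the nematode Caenorhabditis elegans. The protein carried a GFP tag and was expressed from a transgene, and chromatin was collected with an antibody against GFP. That the peaks come from FKH-10 rests on the labels alone. Peaks at the tagged gene and at its marker, which would check the strain, were not analysed on this build, so a mixed or mislabelled strain was not ruled out. The series held 4 samples, namely 2 FKH-10 ChIP samples (replicates 1 and 2) and 2 input samples of total chromatin DNA. The 2 ChIP samples each had a list of peaks, and 1 further list covered the whole series. The inputs had no peak list and entered no comparison. All positions are on WormBase WS220. Genes were not assigned to peaks, because the annotation used here belongs to another build. Peak lists carry no read counts, so the depth of each sample is unknown, and the intervals given are exact (Clopper-Pearson) 95% binomial intervals that cover counting error only. Nothing in the labels says that the replicates came from separate cultures, so differences between their lists may be technical. The p-values come from random placement, random draws or shuffling of peaks and do not measure variation between replicates.

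The series list held 1838 peaks with a median width of 229.5 bp, and 616.862 kb of the genome lay under them. Replicate 1 had 711 peaks with a median width of 215 bp over 265.316 kb. Replicate 2 had 439 peaks, which were wider (median 342 bp) and covered 235.628 kb. Widths in the series list ran from 2 bp to 31619 bp, with quartiles of 151 and 348.75 bp, and 47 peaks were 1000 bp or wider. Peaks under 50 bp numbered 144 in the series list, 72 in replicate 1 and 1 in replicate 2. Each peak carried the authors' own q value, used here only to order peaks within a list. The largest q was 0.000995 in the series list, 0.000999 in replicate 1 and 0.000996 in replicate 2.

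Both replicates called many of the same places, and the strongest places were nearly all shared. Of the 439 peaks of replicate 2, 306 (69.7%, interval 65.17 to 73.97) overlapped a peak of replicate 1. In the other direction 309 of 711 peaks of replicate 1 (43.5%, interval 39.8 to 47.2) overlapped a peak of replicate 2. The 50 peaks with the lowest q in replicate 2 were all shared, as were 45 of the best 50 in replicate 1. Among the best 200 the shared number was 180 in replicate 2 and 157 in replicate 1. Random placement of the other list on the same chromosomes gave a mean of 2.87 shared peaks of replicate 2 and 2.90 of replicate 1, with highest values of 12 and 10 in 10000 placements. The observed overlap was therefore 106.8 and 106.4 times the random mean, and the one-sided permutation p was 0.0001 in both directions, the smallest that 10000 placements can give.

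Shared peaks ranked higher and were wider than peaks called in 1 replicate alone. In replicate 1 the median q percentile (low is strong) was 27.8 for shared peaks and 64.1 for the others, a difference of -36.2 points. The same medians in replicate 2 were 37.2 and 71.1, a difference of -33.8 points. The 2-sided permutation p was 1e-05 in both lists, the smallest that 100000 resamples can give. Median widths of shared and unshared peaks were 301 and 174.5 bp in replicate 1, and 367 and 281 bp in replicate 2. Over the 306 shared pairs the midpoints lay a median of 43 bp apart, and 75.8% lay within 100 bp. The q percentiles of the pairs were correlated across peaks (Spearman's rho 0.544, Pearson's r 0.468, permutation p 0.0001 for each, the smallest that 10000 permutations can give). Peaks are not independent replicates, so these p-values describe the lists only.

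The series list was longer than both replicate lists, and its strongest part was the part seen in both replicates. It covers the whole series, so it probably draws on the same ChIP samples as the replicate lists. A higher overlap at low q is then partly built in and is no independent support. Of its 1838 peaks, 278 (15.1%, interval 13.5 to 16.8) overlapped peaks of both replicates. Another 347 (18.9%) overlapped a peak of replicate 1 alone and 121 (6.58%) a peak of replicate 2 alone. The remaining 1092 (59.4%, interval 57.1 to 61.7) overlapped no replicate peak. When the list was ordered by q and split into deciles, 163 of the 184 peaks in the strongest decile (88.6%, interval 83.1 to 92.8) were in both replicates and 1 was in neither. The share in both was 45.7% in the next decile and 11.4% in the one after it. In the decile that followed, 1 of 184 peaks was in both, while 39.1% overlapped replicate 1 and 14.7% overlapped replicate 2. In the weakest decile 94.5% of peaks were in neither list. Median peak width was 609.5 bp in the strongest decile and 151 bp in decile 9. Within the stricter 50% of the series list the share in both replicates was 29.5% and the share in neither was 29.1%.

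**Figure D1:**
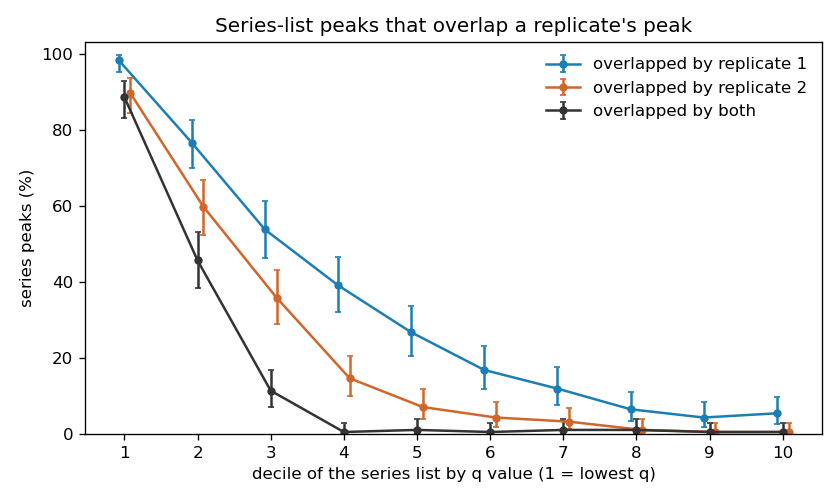
Percent of series-list peaks that overlap a peak of replicate 1, of replicate 2 or of both (vertical axis), by decile of the series list ordered by the authors' q value (horizontal axis, 1 is the lowest q), with exact 95% binomial intervals as error bars. Overlap with both replicates is 88.6% in decile 1, 45.7% in the next and 0.543% in decile 4.

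Most replicate peaks were also in the series list, with 665 of 711 from replicate 1 (93.5%, interval 91.5 to 95.2) and 423 of 439 from replicate 2 (96.4%, interval 94.1 to 97.9). A total of 46 peaks of replicate 1 and 16 of replicate 2 had no counterpart there, and 5 of these places were called in both replicates. These 5 are named after their values were seen. The strongest lay at the right end of chromosome I, at 15063988 to 15067641 in replicate 1 (q 2.71e-154, rank 4) and at 15063979 to 15067630 in replicate 2 (q 4.80e-279, rank 3). This end of the chromosome carries the ribosomal RNA gene array, a repeat at which a call need not mean binding, and whether the place lies in the array was not analysed on this build. In replicate 1 the others were I 933314 to 933712, IV 9046973 to 9047344, X 11787127 to 11787544 and III 1301539 to 1301900, with ranks of 369, 233, 202 and 571. In replicate 2 these places ranked 68, 75, 190 and 321. The place on IV lay within 10 kb of the wide block at IV 9048092 to 9078801 described below, so it may not be separate from it.

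Called bases were concentrated in 6 wide blocks on 5 chromosomes. A block was defined, after the data were seen, as a chain of series peaks with gaps of up to 10 kb that held at least 8 kb of called bases. The smallest of the 6 held 15.452 kb, whereas the next chain in the genome held 3.319 kb. The blocks spanned 21.721 to 40.562 kb each and 192.833 kb together, which is 0.193% of the chromosome length. They held 65 of the 1838 series peaks (3.54%) but 23.4% of all bases called in the series list, and 32 of the 47 peaks of 1000 bp or wider. In replicate 1 they held 41.7% of called bases, and in replicate 2 36.3%.

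The block at I 14719042 to 14759603 was filled almost without a break. It had 37.169 kb called in the series list, 36.674 kb in replicate 1 and 36.806 kb in replicate 2, and held the top-ranked peak of every list. The block at X 16343325 to 16379780 had 34.238 kb called in the series list, which filled 93.9% of its span, with 30.575 kb in replicate 1 and 25.138 kb in replicate 2. The other 4 blocks differed more between the replicates. At II 1644358 to 1674197 replicate 2 had 16.082 kb called and replicate 1 6.511 kb, a ratio of 2.47. At IV 7026768 to 7060311 the direction was opposite, with 14.474 kb in replicate 1 and 1.25 kb in replicate 2, a ratio of 11.6. At IV 9048092 to 9078801 replicate 1 had 13.584 kb and replicate 2 5.95 kb, a ratio of 2.28. At V 18704364 to 18726084 replicate 1 had 8.839 kb and replicate 2 0.255 kb, a ratio of 34.7. Outside the blocks the replicates covered 154.659 kb and 150.147 kb. With 1 list per replicate, these differences between replicates have no test. The native fkh-10 gene is on chromosome I and unc-119, the rescue marker, on III, by the chromosomes listed in the WBcel235 annotation, so 5 of the 6 blocks were on other chromosomes than fkh-10 and 0 were on that of unc-119. An informal look at positions on that other build gave no sign that the 1 block on I lies over fkh-10. That look set positions of different builds side by side, so it is a doubt and not a result. Whether the blocks belong to this strain is not settled here.

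**Figure D2:**
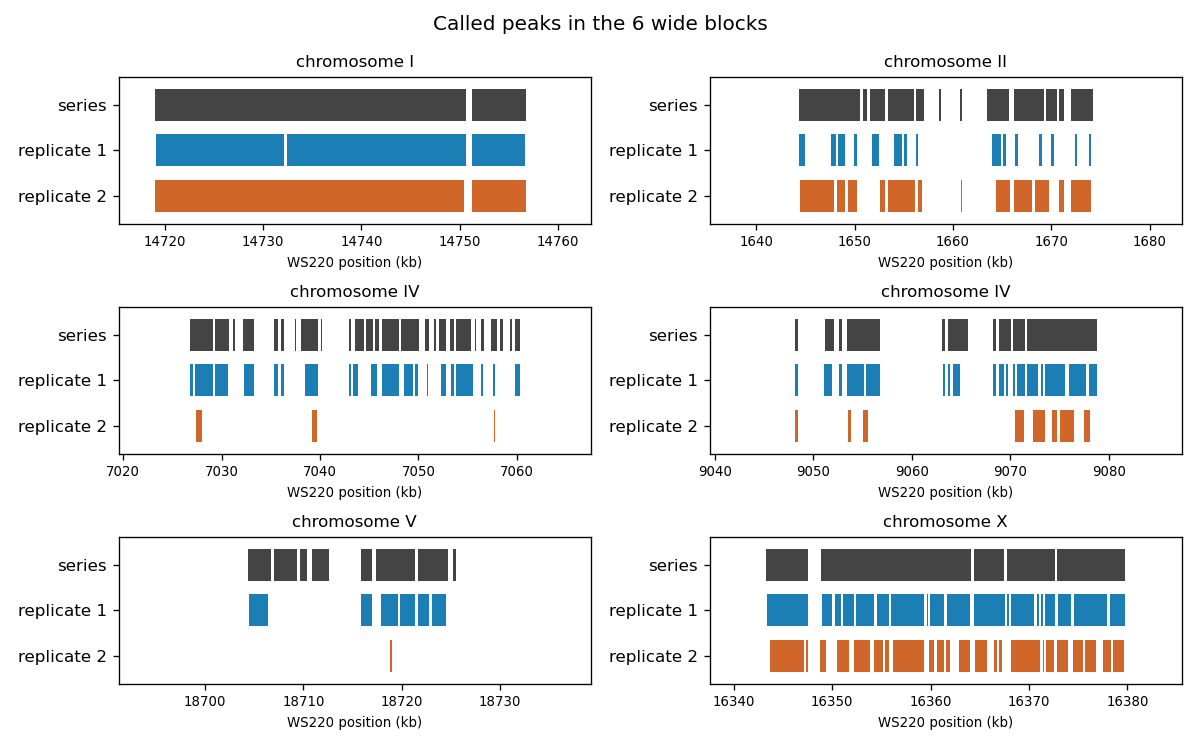
Called peaks (bars, to scale) of the series list and of replicates 1 and 2 in the 6 wide blocks, against WS220 position in kb, with 1 panel per block. Replicates 1 and 2 cover 36.674 and 36.806 kb of the chromosome I block, and 8.839 and 0.255 kb of the chromosome V block.

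The 20 highest-ranked series peaks that overlapped both replicates were taken as named places. Blocks held 16 of them, namely 5 of the 6 on X, 5 of the 6 on II, 3 of the 4 on IV, both on I and the 1 on V. The widest was I 14719042 to 14750660, at 31619 bp. On X the strongest was 16348895 to 16364075, 15181 bp wide, and both it and the widest peak had a listed q of 0. The 4 named peaks outside blocks were X 11605373 to 11606711 (1339 bp, q 2.95e-65), IV 14032452 to 14034470 (2019 bp, q 2.54e-62), II 14804244 to 14804838 (595 bp, q 8.85e-30) and III 3867368 to 3867707 (340 bp, q 7.96e-29). Their ranks were 12, 14, 35 and 33 in replicate 1 and 13, 10, 30 and 31 in replicate 2.

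Because blocks took most of that list, the 20 highest-ranked shared peaks outside blocks were also described, a choice made after the values were seen. They ranked between 11 and 46 in the series list, and their widths ran from 340 to 2019 bp with a median of 713.5 bp. Chromosome II held 7 of them, III held 4, and IV, V and X held 3 each, while none lay on chromosome I. On chromosome V they included 12303418 to 12303813 (q 8.37e-25) and 5284005 to 5285459, which ranked 19 in replicate 1 and 7 in replicate 2. On chromosome III they included 10989268 to 10989941, 13070390 to 13071025 and 7446778 to 7447878. A pair on chromosome II, 11746561 to 11747272 and 11749315 to 11750401, lay close together. The first of that pair ranked 27 in replicate 2 and 589 in replicate 1, the lowest rank in either replicate among the 20.

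Peaks were unevenly spread over the chromosomes, with few on I and many on III. Chromosome I held 144 series peaks (7.83%, interval 6.65 to 9.16) on 15.1% of the length, or 0.521 of the number its length gives. Chromosome III held 377 (20.5%, interval 18.7 to 22.4) on 13.8% of the length, 1.49 times that number. The same direction held in both replicates, where chromosome I had 22 peaks (0.206 of the number given by length) in replicate 1 and 17 (0.257) in replicate 2. Chromosome III stood at 1.48 in replicate 1 and 1.52 in replicate 2. Chromosome X was above its length share in the series list (1.15), in replicate 1 (1.30) and in replicate 2 (1.63), and chromosome V was below it in all lists (0.754, 0.735 and 0.656). Benjamini-Hochberg adjusted random-draw p over the 6 chromosomes was 0.0002 for I, III and V in the series list and 0.0052 for X. In the replicates it was at most 0.0006 for these 4 chromosomes. Chromosome II was at 1.20 in the series list (adjusted p 0.0003) and 1.19 in replicate 1 (adjusted p 0.045), and at 1.15 in replicate 2 it did not pass (adjusted p 0.23). Chromosome II also did not pass in replicate 1 outside the blocks (1.19, adjusted p 0.056), or in the series list with chains of neighbouring peaks as units (1.12, adjusted p 0.093). Chromosome IV did not pass in any of the 3 lists (adjusted p 0.93, 0.067 and 0.23). Chromosome length was taken as the largest peak end in any list, since no genome of this build was used.

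**Figure D3:**
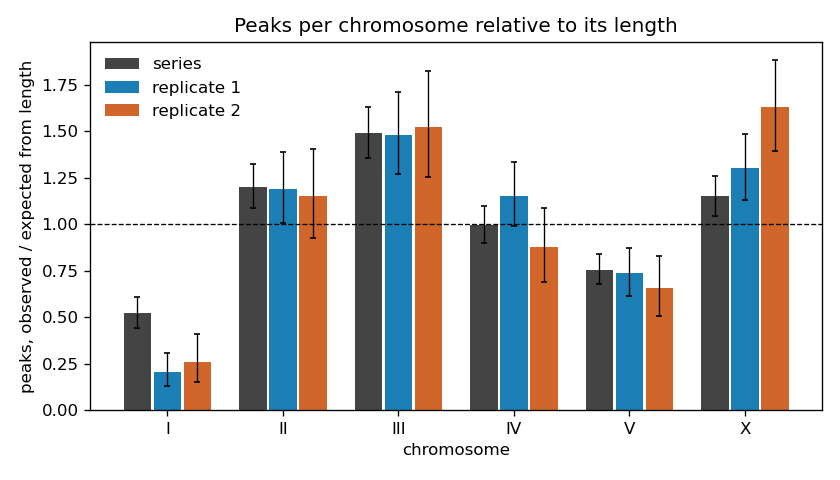
Peaks on each chromosome divided by the number its length gives (vertical axis, dashed line at 1) for the series list and for replicates 1 and 2, with exact 95% binomial intervals as error bars. Chromosome I stands at 0.521, 0.206 and 0.257, and chromosome III at 1.49, 1.48 and 1.52.

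Along the autosomes, peaks lay somewhat more often in the chromosome centres than length gives. Of 1466 autosomal series peaks, 535 (36.5%, interval 34.02 to 39.02) had their midpoint in the middle 33.3% of the length. This was an excess of 3.16 points (2-sided random-draw p 0.012). The excess was 6.995 points in replicate 1 (221 of 548 peaks, random-draw p 0.0008) and 6.92 points in replicate 2 (126 of 313, random-draw p 0.0091). Outside the blocks the call ended in the series list (2.16 points, random-draw p 0.093) and in replicate 1 (3.93 points, random-draw p 0.077). It also ended in these lists with chains of neighbouring peaks as units (2.09 and 3.57 points, random-draw p 0.17 and 0.13). Replicate 2 kept the call in both settings.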

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

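The alternatives outside the 6 blocks, with shifted lists, with peaks of at least 50 bp and with chains of peaks as units were chosen after the results were seen, and the others were planned. Of 73 alternative values, 60 kept their side of the threshold (called values also their direction) or stayed within counting error, 7 lost their call, 6 moved and 0 reversed. Replicate overlap passed at permutation p 0.0001 in every alternative run, with 56.9% to 72.6% of replicate 2 peaks and 37.1% to 56.9% of replicate 1 peaks shared. Both rank differences and the deviations of chromosomes I, III, V and X also kept their calls in every alternative run. The excess on chromosome II lost its call with chains of peaks as units (1.12, adjusted random-draw p 0.093) and in replicate 1 outside the blocks (1.19, adjusted random-draw p 0.056). For the chromosomes and the middle of the autosomes, leaving 1 replicate out meant taking the list of the other alone. Those values, counted among the 73, repeat the replicate values given above. For chromosome II they were 1.15 in replicate 2 (adjusted random-draw p 0.23) and 1.19 in replicate 1 (adjusted random-draw p 0.045). The cause of the lost calls on chromosome II was not tested. Within the stricter 50% of the series list, the share of its peaks in both replicates rose from 15.1% to 29.5% and the share in neither fell to 29.1%, as the deciles by q show. Without 1 replicate the share counts overlap with the remaining list alone, so it moved by construction, to between 21.7% and 34.004% for supported peaks and between 66.0% and 78.3% for unsupported ones. The excess in the middle 33.3% of the autosomes was 3.16 points in the series list. It was 2.16 points outside the blocks (random-draw p 0.093) and 2.09 points with chains of peaks as units (random-draw p 0.17). In replicate 1 it fell from 6.995 to 3.93 points (random-draw p 0.077) and 3.57 points (random-draw p 0.13), and the cause was not tested. In replicate 2 it kept its call at 6.88 and 8.01 points (random-draw p 0.015 and 0.007). No paired analysis was possible because the inputs, which share replicate numbers with the ChIP samples, have no peak list in the data used here. Promoter share, annotation classes, gene lists, the forkhead motif, noncoding RNA genes, transgene loci and placement at promoters were not run, since builds differed. Without read counts, it cannot be said how far depth sets the number of peaks in each list.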

Other observations

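Tests of a single insert, of extra DNA copies, of block length, of lost calls on chromosome I and of a more sensitive replicate were chosen after the results were seen, and the other 3 were written before their results, although blocks and chains of peaks, which they use, were defined after the data were seen.

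The number of series peaks in both replicates did not follow independent overlap in every decile. In decile 3 of the series list 21 peaks were in both replicates, against 35.5 if the replicates had overlapped it independently, and in decile 4 the numbers were 1 and 10.6. In decile 1 they were 163 and 162, and in decile 2 they were 84 and 84.3. Deciles 7 to 10 went the other way, with 2, 2, 1 and 1 peaks against 0.717, 0.130, 0.0435 and 0.0546. These values were picked out after they were seen, and no test was run. If the series list pools both replicates, ordering by its q can itself give a deficit, and how that list was made is not given in the sources used here.

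The 6 wide blocks held more called bases than any other chain of peaks in the series list. Chance clustering within a single replicate was excluded as the whole cause. The 6 chains with most called bases in replicate 1 held 85.9 kb of the called bases of replicate 2. In 1000 random placements the median was 0 and the highest value 36.806 kb (permutation p 0.001, the smallest these placements can give). The test sums over the 6 chains, so it cannot decide for a single block. Replicate 2 had only 1.25 kb called in the block at IV 7026768 to 7060311 and 0.255 kb in that on V. Replicate 1 had 22 peaks in the 33.544 kb of that block on IV and 6 peaks in the 21.721 kb of the block on V. Over the whole of IV and V it had 8.18 and 5.22 peaks per Mb. These values argue against peaks of replicate 1 placed independently at random in these 2 blocks. Clustering peculiar to replicate 1 stays open there, since replicate 2 called so little. A single transgene insert with its marker would give at most 2 wide blocks. More than that, 4 blocks, had at least 5 kb called in both replicates, but this cut was chosen after the results were seen. The count depends on it, since replicate 1 had 6.511 kb in the block on II. Replicate 2 had 5.95 kb in the block at IV 9048092 to 9078801. At the 8 kb used to define blocks, only those on I and X pass in both replicates. A single insert as the whole cause is thus in doubt but not excluded. Since 0 blocks were on the chromosome of native unc-119 and 1 was on that of fkh-10, an insert is in doubt for the 5 blocks elsewhere. For the block on I the only doubt is the informal look at another build, which is not a result, so an insert stays open there. Extra DNA copies of long fragments may underlie blocks with fixed ends, but the 12 edges of all 6 blocks differed between replicates by a median of 224.5 bp, with at most 660 bp in those 4 blocks (median 46 bp) and 652 to 14276 bp in the other 2, where replicate 2 had 3 peaks and 1 peak. Shared edges would also come from broad binding, and carry-over of DNA from other tagged strains, or a mixed or mislabelled strain, was not tested, so these cannot be told apart while input signal and gene positions of this build are not analysed here.

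The blocks also differed between the replicates. Greater sensitivity of a single replicate at every block was excluded as the whole cause, since replicate 2 had 2.47 times the called bases of replicate 1 on II but 0.0864 and 0.0288 times on IV (7026768 to 7060311) and V. Outside the blocks the ratio of called bases was 0.971, although replicate 1 had 627 peaks there and replicate 2 had 389. Differences in the material between the replicates stay open and untested, and no biological explanation was tested.

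Chromosome I had few peaks, and dense clusters elsewhere were excluded as the whole cause. With chains of peaks as units, chromosome I still had 0.607 of the number given by length (adjusted random-draw p 0.0002). With similar block cover, X and IV had 2.22 (interval 1.83 to 2.72) and 1.73 (interval 1.41 to 2.13) times as many peaks per Mb outside blocks. An effect of the block on I stays open all the same. The comparison needs the chromosomes to share 1 density otherwise, which was not tested. It also matches called bases and not strength, and the block on I held the top-ranked peak of every list. Series peaks of chromosome I outside blocks overlapped a replicate peak in 16.3% of cases (23 of 141) against 41.2% elsewhere, and the rates of the same q deciles on other chromosomes would give 47.4 peaks (one-sided permutation p 0.0001, the smallest 10000 permutations can give). The gap thus remained at matched q, but it restates the lower chromosome I counts of the replicates, and calls lost in the single replicates cannot be told apart from calls added in the series list. A generally lower sensitivity there also stays open, since the median q percentile of its peaks was 6.01 points weaker but the permutation p was 0.16, and no biological explanation was tested.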
